A study of Mus musculus with 12 samples.

How the data were processed

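RNA from mouse erythroleukemia (MEL) cells, an erythroid leukemia line that matures toward red cells when given dimethyl sulfoxide (DMSO), was hybridized to Affymetrix mouse expression arrays. The labels name 3 wild type and 3 G9a knockdown hybridizations, numbered 1 to 3 in each group. Per the labels' protocols, 2% DMSO was added for 4 days, and the knockdown was induced with 5 µg/ml of doxycycline. The labels give the same protocol text for both groups and do not say whether the wild type cells also received doxycycline. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be in part technical.

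Each hybridization was deposited in 2 summaries, per the labels: MAS5 and GCRMA. The 12 deposited columns are therefore 6 arrays summarised in 2 ways, and the summaries were never counted as further replicates. The deposited MAS5 columns hold intensity on a linear scale, and the 2% trimmed mean of each array was 500, so the authors' values had been scaled to a common target. The deposited GCRMA columns hold log2 values, from 0.69 to 16.49. Software versions and the GCRMA settings are not given in the sources used here. Deviations from the mean of the 6 arrays correlated better between the summaries of one array (0.633 to 0.754) than with any other array (at most 0.393). No 2 columns held identical values.

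Of 45101 probe sets, 64 control probe sets were left out of all tests. Gene names came from the platform annotation supplied with the series, which names 1 gene for 34958 probe sets, several genes for 932 and none for 9211. Gene identifiers were looked up in a RefSeq gene table of the GRCm38.p6 assembly, where 99.4% matched and 0 symbols changed. The files name no genome build, so the table served for names and for the order of genes along chromosomes, and no coordinates are given. No gene is named from a probe set with several genes.

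The main comparison used GCRMA values and limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, Benjamini-Hochberg adjustment, threshold 0.05). Probe sets above log2 4 in at least 3 of the 6 arrays were tested. These were 17028 probe sets, of which 15581 carried 1 gene, 490 several and 957 none, covering 9025 genes. A gene was represented by its tested probe set with the highest mean over the 6 arrays. The text says where another tested probe set of a gene whose difference is given had the opposite sign or under 50% of that difference. The MAS5 values were tested in the same way as log2(value + 1), and MAS5 differences are on that scale. Gene lists were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated from the data, and with fry. The 3′ to 5′ ratios of control transcripts were compared by two-sided exact permutation tests, in which 3 against 3 arrays cannot give a p below 0.10.

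The tests, the alternatives and 23 gene lists were fixed before the data were examined. The lists covered histone H3 lysine 9 methylation, globins, heme and iron, erythroid transcription factors, red cell membrane and terminal differentiation, stem and progenitor genes, cell cycle, p53 targets with inhibitors of cyclin-dependent kinases, germline genes, imprinted genes, polycomb repressive complex 2, DNA methylation, Mediator, interferon response, amino acid and mitochondrial stress, autophagy and lysosome, sterol synthesis, and glycolysis and hypoxia. Markers of myeloid, megakaryocyte, lymphoid, mast cell and basophil, and fibroblast or endothelial cells were listed as signs of other cell types. Of these, 21 lists had at least 2 measured genes and were tested.

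The rule for genes named in the text, also fixed beforehand, took every Ehmt2 and globin probe set, up to 4 members of each list by lowest p, and 12 genes in each direction by size of change. Those 12 had to pass the threshold, have groups that did not overlap, and keep their sign in MAS5. As 0 genes qualified through their representative probe set, the 12 in each direction were filled by lowest unadjusted p and are given as values.

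The replicate numbers were checked for pairing. Deviations from the group mean correlated at 0.72, 0.57 and 0.37 between wild type and knockdown arrays of the same number, and at −0.59 to 0.17 between arrays of different numbers. Both replicate 1 arrays stood apart, which by itself lowers the correlations between number 1 and the others. Between numbers 2 and 3 the correlations were 0.17 and 0.13, below the same-number 0.57 and 0.37. Before centring, knockdown 3 correlated at 0.9893 with wild type 2 and at 0.9883 with wild type 3. The numbers therefore appear to pair the samples, least clearly for number 3. The main fit, fixed beforehand, has no block and leaves this pairing out. This pairing comes from the data, since the labels do not say what a number stands for. Values with the replicate number as a block are given where they change a call or a count.

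The pipeline was tested on simulated data with the real probe sets' means and spread and no effect of the replicate number, in which 200 of 17028 probe sets were changed. It recovered 66.2% of 2-fold, 95% of 2.83-fold, 95% of 4-fold and 100% of 8-fold changes, with 9 false calls. With the replicate number as a block it recovered 43.8% of 2-fold and 90% of 2.83-fold changes, which does not show how the block performs on arrays that the numbers pair. With 200 changed probe sets the adjustment is less strict than with few, so these shares do not carry over to data with few changes. In the real data the brighter Ehmt2 probe set, 7.31-fold lower, did not pass (limma adjusted p = 0.0719). Alternatives covered the summary, the filter, further normalization, the variance model, array weights, the replicate block, the probe set per gene, the threshold, the pseudocount and each array left out. Others were added after seeing the data: both replicate 1 arrays left out, chromosomes 1, 3 and 12 left out, the estimated correlation combined with the block, and other pseudocounts and filters for the correlation of summaries. Neighbouring genes were scanned in windows along the chromosomes, also after seeing the data, with odd-numbered genes used to find blocks and even-numbered genes to measure them. Arrays carry no read depth, and their number limits the precision. Between 37.6% and 38.1% of probe sets lay above the filter's log2 value in each array.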

Results

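Gene expression was measured in MEL cells under DMSO-induced erythroid differentiation, in 3 wild type arrays and 3 arrays of cells with knockdown of G9a. G9a is the histone H3 lysine 9 methyltransferase encoded by Ehmt2. The series is titled for the role of G9a in β-globin expression, and the comparison the design implies is knockdown against wild type. Values below are GCRMA log2 values, as mean ± SD with n = 3 per group unless stated, and differences are knockdown minus wild type.

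Ehmt2 mRNA was lower in every knockdown array than in any wild type array. At probe set 1426888_at it fell, from 7.11 ± 0.30 in wild type to 4.24 ± 0.068 in the knockdown, a log2 difference of −2.86 (95% interval −3.27 to −2.46, limma adjusted p = 0.0216). The knockdown level there is close to the filter at log2 4, and no fold is given for it. The brighter Ehmt2 probe set, 1460692_at, read 10.06 ± 0.16 and 7.19 ± 0.47, a difference of −2.87 (−3.45 to −2.29), or 7.31-fold lower. That probe set did not pass the threshold in the unblocked limma fit (adjusted p = 0.0719) and passed with the replicate number as a block (adjusted p = 0.0316). Ehmt1, which encodes the partner methyltransferase GLP, read 8.76 ± 0.14 and 8.86 ± 0.099, with an interval of −0.19 to 0.39 for the difference. In MAS5 the Ehmt2 differences were −2.71 and −2.46, with adjusted p of 0.743 and 0.349 in limma. The call for 1426888_at held without wild type replicate 1 (adjusted p = 0.035) and ended when any of the other 5 arrays was left out (adjusted p 0.0579 to 0.322 in limma), with differences of −3.01 to −2.70 throughout.

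**Figure D1:**
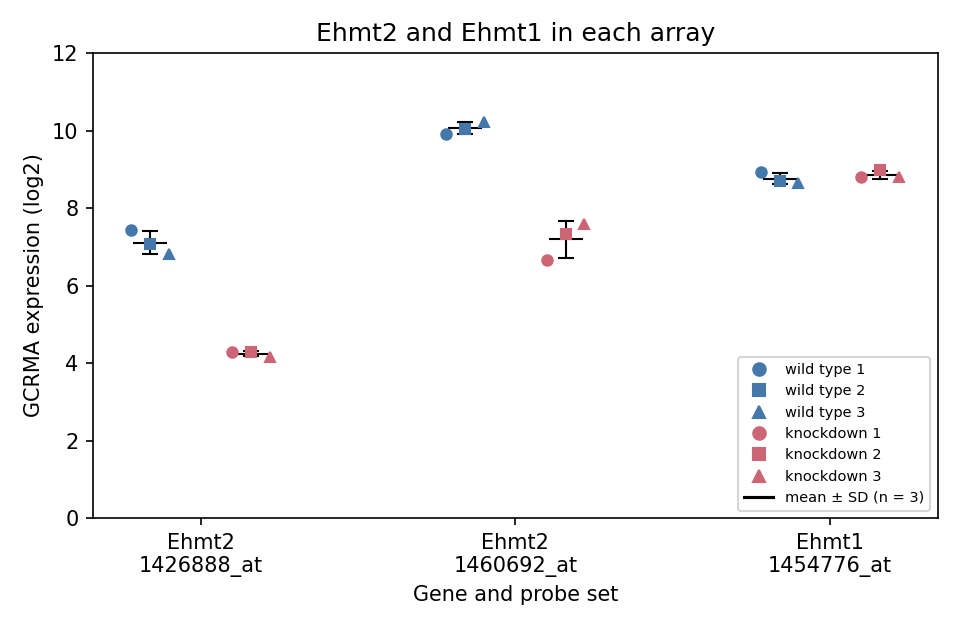
GCRMA expression (log2) of the Ehmt2 and Ehmt1 probe sets in each array, wild type in blue and knockdown in red, with marker shape for the replicate number and black bars for mean ± SD (n = 3). Both Ehmt2 probe sets lie lower in all 3 knockdown arrays, by 2.86 and 2.87 log2 units on average, while the Ehmt1 groups overlap.

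Across the array, Ehmt2 was the only gene called. Of 17028 probe sets tested, 1 passed the threshold in the limma fit (0 higher, 1 lower), and 2 passed with the replicate number as a block, both of them Ehmt2. In MAS5, 0 passed with or without the block. At an unadjusted p under 0.05 there were 999 GCRMA probe sets (441 higher and 558 lower, 851 expected by chance) and 1101 MAS5 probe sets (588 higher and 513 lower, the opposite balance). With the block, the GCRMA count was 2329 and the MAS5 count 1799. The groups did not overlap for 12.4% of probe sets, against 10% by chance. At an unadjusted p under 0.001, 30 of the 37 GCRMA probe sets were lower in the knockdown, and 69 of 97 with the block.

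The genes lower in the knockdown with the lowest p after Ehmt2 included Fis1, a mitochondrial outer membrane protein that acts in mitochondrial fission. It read 11.31 ± 0.14 in wild type and 10.17 ± 0.13 in the knockdown, and its other probe set, 1443819_x_at, differed by −1.37 (limma adjusted p = 0.0719). Fis1 was called at that probe set with the stricter filter on dim probe sets and with array weights, where 3 probe sets passed. Atxn10 (ataxin 10) differed by −1.16 (SE 0.15). It had the same sign at all 4 of its tested probe sets in GCRMA (−0.51 and −0.31 at the 2 dimmest) and a limma unadjusted p under 0.05 at 3. In MAS5 its dimmest probe set had the opposite sign. The transcript A830082K12Rik differed by −1.28. The endoplasmic reticulum chaperone Erp29 differed by −0.92, the translation repressor Eif4ebp2 by −0.93 (by −0.45, −0.29 and −0.15 at its other probe sets), and the ubiquitin-conjugating enzyme Cdc34 by −0.73. The zinc finger genes Zfp60 and Zfp120 differed by −0.85 and −0.77. The knockdown level of Zfp60, 4.28 ± 0.078, is close to the filter at log2 4. Uxs1, which makes UDP-xylose, differed by −0.71, the actin-binding Pfn2 by −0.63, and 2810004N23Rik by −0.81 (−0.057 at its other probe set). Adjusted over all probe sets, the representative probe sets of these 12 genes, Ehmt2 included, had limma p-values of 0.0719 to 0.458.

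Among genes higher in the knockdown, the largest difference of the 12 with the lowest p was that of 3110040M04Rik, at 1.99 (SE 0.39), from 5.92 ± 0.75 to 7.91 ± 0.35. Uros, the uroporphyrinogen III synthase of heme synthesis, read 7.24 ± 0.083 and 8.05 ± 0.10, a difference of 0.82 (SE 0.11). The galectin gene Lgals7 differed by 1.05. The transcription factor genes Fosl2, Egr1 and Cebpg differed by 0.87, 0.63 and 0.58 (Cebpg by 0.074 at its other probe set, where the groups overlap), and the immediate early gene Ier5 by 0.56 (SE 0.11). Syt14 differed by 0.72, Tinagl1 by 0.62, Rnf157 by 0.56 (0.27 at its dimmest probe set) and Rhobtb2 by 0.49. The RNA-binding protein gene Mex3c differed by 0.56 at one probe set and by −0.31 at its dimmer one. None of the 12 passed the threshold (limma adjusted p 0.351 to 0.537). In all 24 genes of both directions the groups did not overlap, and the MAS5 difference had the same sign, although that of Rhobtb2 was 0.037. Neither is independent support, since choosing genes by lowest p favours groups that do not overlap, and both summaries share the arrays.

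The globin genes, the subject of the series' title, were not called in either direction over all probe sets. The probe set annotated to several adult β-globin genes, 1417184_s_at, read 15.02 ± 0.016 in wild type and 14.99 ± 0.18 in the knockdown, a difference of −0.026 (95% interval −0.32 to 0.27). In MAS5 the same probe set differed by 0.32 (limma adjusted p = 0.807), with all 3 knockdown arrays above all 3 wild type arrays (two-sided exact permutation p = 0.10, the smallest possible with 3 against 3), so its sign depends on the summary. The 3 probe sets annotated to both adult α-globin genes differed by −0.072, 0.063 and 0.048 in GCRMA and by 0.26, 0.27 and 0.084 in MAS5. Hbb-b2, an adult β-globin gene, had probe sets of opposite sign: 1427865_at read 9.37 ± 0.24 and 9.85 ± 0.27, a difference of 0.48 (0.028 to 0.93), and 1427866_x_at differed by −0.30 (−1.14 to 0.55), ranging from −0.70 without wild type replicate 1 to −0.031 without wild type replicate 2. Hba-a2 at 1427219_at differed by 0.028. Of 15 globin probe sets, 7 passed the filter, and 0 passed the threshold (smallest limma adjusted p = 0.831) or when adjusted over the list alone (0.284). With the replicate number as a block, 1 passed when adjusted over the list alone, Hbb-b2 at 1427865_at (adjusted p = 0.0293), and 0 over all probe sets (smallest adjusted p = 0.209). Probe set 1417184_s_at lies at the 99.7th percentile of all probe sets and reads several near-identical genes, which it cannot separate. Whether signal this near the top of the range still follows the amount of RNA was not tested. The shift between summaries was not limited to globins: Fth1, at 15.81 ± 0.067 in wild type, differed by −0.058 in GCRMA and by 0.23 in MAS5.

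Embryonic globin transcripts lay below the filter in both groups, near the array medians of 2.99 to 3.10. Hbb-bh1 and Hba-x read between 2.72 and 3.03 on average, and the Hbb-y probe sets between 2.62 and 3.21. At 1436823_x_at, Hbb-y read 2.98 ± 0.079 in wild type and 3.21 ± 0.19 in the knockdown, with all 3 knockdown arrays above all 3 wild type arrays in both summaries (two-sided exact permutation p = 0.10 in each). The Hbb-y probe set 1436717_x_at did so in MAS5 (exact p = 0.10) and not in GCRMA (exact p = 0.90). At the third Hbb-y probe set, 1450621_a_at, the groups overlapped in both summaries. It differed by −0.044 in GCRMA (exact p = 0.40), with an exact p of 0.90 in MAS5. The remaining adult probe set, for Hba-a1 at 1453574_at, also lay below the filter.

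**Figure D2:**
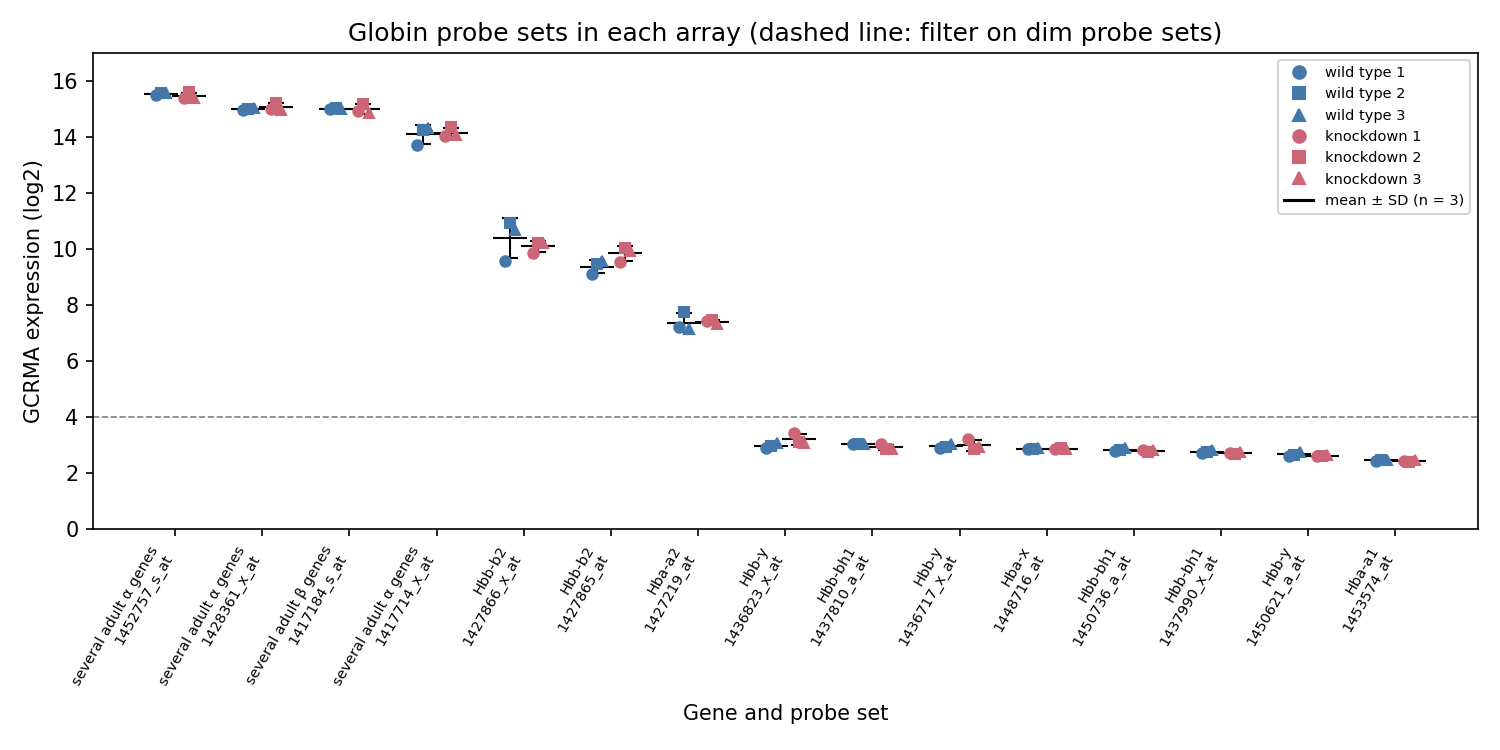
GCRMA expression (log2) of the 15 globin probe sets in each array, wild type in blue and knockdown in red, with black bars for mean ± SD (n = 3) and a dashed line at the filter of log2 4. The adult probe sets near log2 15 and the embryonic ones near log2 3 have overlapping groups, apart from the dim Hbb-y probe set 1436823_x_at.

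Of 21 measured genes of the red cell membrane and of terminal erythroid differentiation, 18 had a positive difference, with a median of 0.25, and the list rose by camera with the preset correlation (adjusted p = 4.56e-04). With an estimated correlation the adjusted p = 0.859. With the replicate number as a block these were 6.65e-06 and 0.822. The list also passed in 3 of the 9 other splits of the arrays into 3 and 3, with a lower adjusted p than the real split in 2 (lowest 7.13e-05). Such a call can thus arise from other groupings. These splits also hold knockdown and replicate differences, so they cannot tell whether the knockdown is its source. No single member passed, over all probe sets or adjusted over the list alone. With the replicate number as a block, 6 passed when adjusted over the list alone: Ermap, Rhd, Icam4, Dmtn, Kel and Car1. The carbonic anhydrase gene Car1 read 6.87 ± 0.96 in wild type and 8.81 ± 1.18 in the knockdown, a difference of 1.94 (1.27 without knockdown replicate 1). The blood group and membrane protein genes Ermap and Kel differed by 0.74 and 0.73 (Kel by 0.46 without knockdown replicate 2), and the membrane skeleton gene Add2 by 0.90 (0.19 to 0.68 at its other probe sets). The median deviation of the list from the mean of all arrays was 0.0030, 0.030 and −0.30 in wild type replicates 1 to 3 and 0.078, 0.27 and 0.069 in the knockdown. The list's median was 0.13 with array weights (adjusted p = 0.0119).

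Erythroid transcription factor genes had a positive difference in 18 of 24 members, with a median of 0.13, and the list rose by camera with the preset correlation (adjusted p = 0.0127; adjusted p = 0.859 with an estimated correlation). In 1 of the 9 other splits it passed with a lower adjusted p (0.0013). No member passed when adjusted over the list alone, and Lmo2 passed with the block. Lmo2 and Ldb1, which encode partners in the erythroid GATA1 complex, differed by 0.63 and 0.23. Klf3 and Stat5b differed by 0.32 and 0.40 (−0.015 and 0.099 at their dimmest probe sets). The list's call ended without wild type replicate 1 (adjusted p = 0.142), wild type replicate 3 (0.0515) or knockdown replicate 2 (0.0806), and when both replicate 1 arrays were left out (0.139).

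Heme and iron genes did not pass as a list, with 13 of 21 positive, a median of 0.091 and a camera adjusted p of 0.308. Uros rose when adjusted over the list alone (adjusted p = 0.0041), and 3 genes passed so with the block, Ppox, Uros and Steap3. The mitochondrial iron importer gene Slc25a37 differed by 0.55, the iron regulatory gene Ireb2 by 0.33, and the transferrin receptor gene Tfrc by −0.23.

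Of 15 measured interferon response genes, 14 had a negative difference, with a median of −0.16, and the list fell by camera with the preset correlation (adjusted p = 0.0127; adjusted p = 0.859 with an estimated correlation). It passed in 3 of the 9 other splits, each with a lower adjusted p (0.0102, 0.0018 and 0.0016), so the splits cannot tell whether the knockdown is the source of this call either. No member passed, adjusted over the list alone or over all probe sets. Oasl2 read 6.39 ± 0.64 in wild type and 4.81 ± 1.07 in the knockdown. Rsad2 differed by −0.89, Usp18 by −0.85 and Irf7 by −0.56, and without knockdown replicate 3 Rsad2 differed by −0.57 and Irf7 by −0.26. The list's call ended without wild type replicate 1 (adjusted p = 0.0869) or knockdown replicate 3 (0.455), and its median was −0.30 without knockdown replicate 1.

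**Figure D3:**
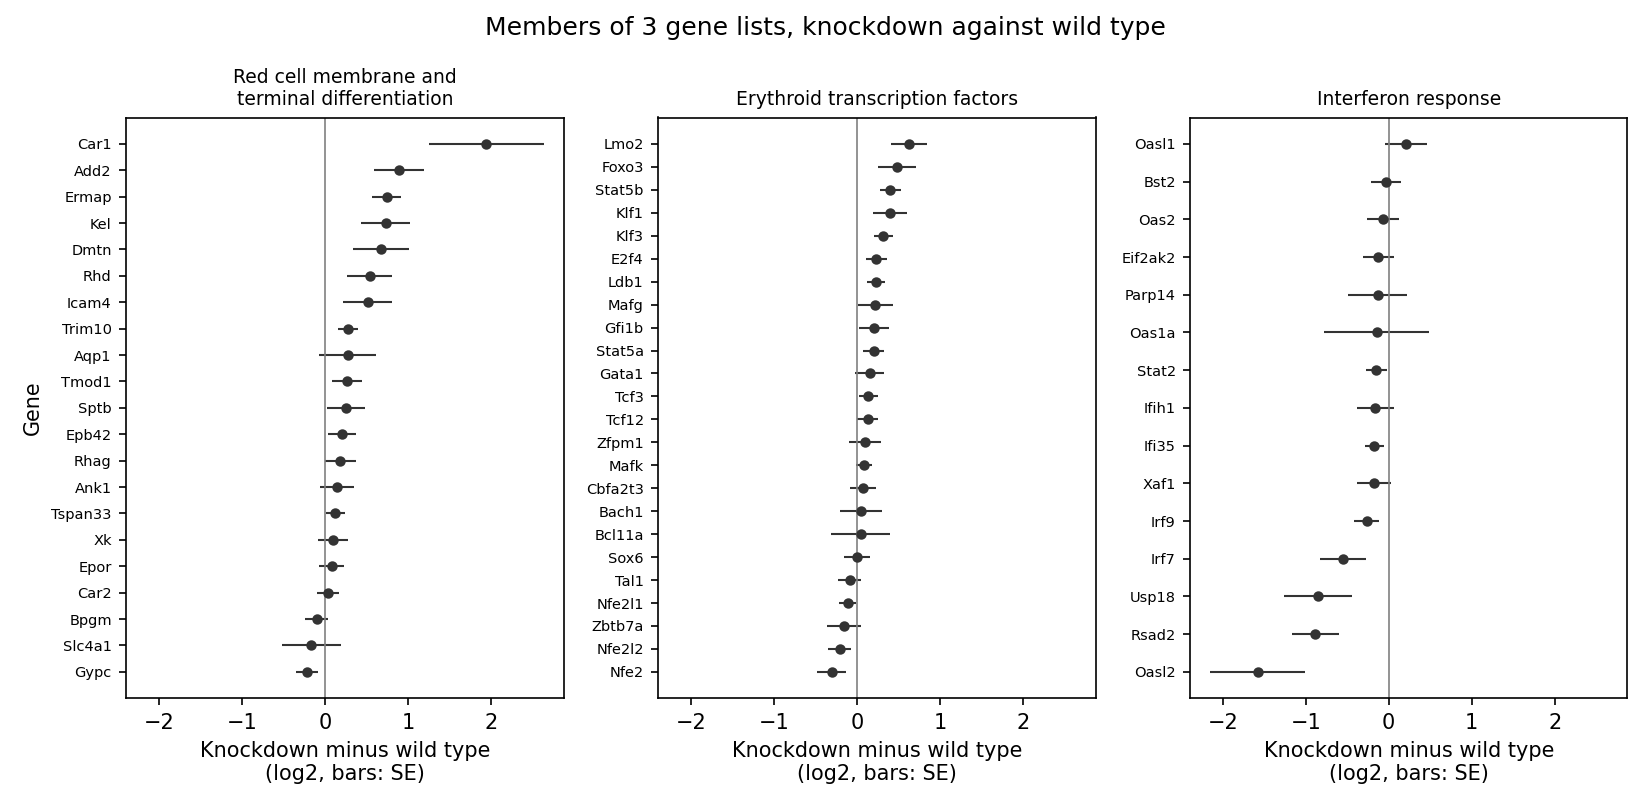
Difference between knockdown and wild type (log2, points) with its standard error (bars) for each measured member of 3 gene lists. Differences are positive for 18 of 21 red cell genes and 18 of 24 erythroid transcription factors, and negative for 14 of 15 interferon response genes.

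The other chromatin lists did not pass as groups. In the histone H3 lysine 9 methylation list, 11 of 20 were positive (camera adjusted p = 0.784), and Ehmt2 was the one gene that passed when adjusted over the list alone, joined by Uhrf1 with the block. Cdyl, a reader of methylated lysine 9, differed by 0.34 (0.22 without knockdown replicate 3, and 0.14 at each other probe set), the heterochromatin gene Cbx5 by −0.26 and the demethylase gene Kdm1a by 0.20. Polycomb repressive complex 2 genes had 6 of 9 positive (adjusted p = 0.682), with Aebp2 at 0.25. DNA methylation genes had 7 of 11 negative (adjusted p = 0.732), with the helicase gene Hells at −0.72, and Uhrf1 and Hells passed over the list alone with the block. Only 3 of 32 germline genes were measured, all negative (adjusted p = 0.341), with Tex19.1 at −0.86. Imprinted genes had 8 of 13 negative (adjusted p = 0.872, with a MAS5 median of 0.11 against −0.032 in GCRMA). Phlda2 differed by 0.67 and Igf2r by −0.83, and with the block Phlda2 and Kcnq1ot1 passed over the list alone, Kcnq1ot1 with −0.51 at that probe set and 0.049 and 0.24 at the others. Mediator genes had 16 of 30 negative (adjusted p = 0.732), with Cdk8 at −0.26 (−0.16 without knockdown replicate 1).

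Growth and stress lists did not pass either. Cell cycle genes had 19 of 32 negative (camera adjusted p = 0.682). The nucleotide synthesis gene Rrm2 differed by −1.16 and the cyclin gene Ccne2 by −0.48 (−0.30 without knockdown replicate 2), and both passed over the list alone with the block, as did Mcm5. The list of p53 targets and inhibitors of cyclin-dependent kinases had 10 of 17 negative (adjusted p = 0.81), with Zmat3 at −0.49. Genes of the amino acid and mitochondrial stress response had 17 of 24 negative (adjusted p = 0.406). Atf3 was at 1.12 against that direction, and Psat1 and Atf3 passed over the list alone with the block. Glycolysis and hypoxia genes had 13 of 18 positive (adjusted p = 0.0747), with Ndrg1 at 0.54 and Slc2a3 at 0.45. Autophagy and lysosome genes had 12 of 24 positive (adjusted p = 0.677), with Wipi2 at 0.30 in GCRMA and −0.036 in MAS5, and at −0.20 at its other probe set. Sterol synthesis genes had 11 of 18 negative (adjusted p = 0.338), with Lss at −0.36 and 0.17 at its 2 probe sets.

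Few markers of other cell types were measured above the filter. The megakaryocyte integrin gene Itga2b read 11.86 ± 0.22 in wild type and 11.15 ± 0.28 in the knockdown, and fell when adjusted over the list alone (limma adjusted p = 0.0451) but not over all probe sets (0.684). With 5 of 6 members negative, the megakaryocyte list did not pass (camera adjusted p = 0.338), and F2r differed by −0.30 (−0.45 without wild type replicate 2 and −0.051 without wild type replicate 3). Of 24 myeloid markers, 4 were measured (adjusted p = 0.682, 2 positive), with Prtn3 at 1.19, which passed over the list alone with the block. Of the fibroblast and endothelial markers 3 were measured (adjusted p = 0.682), with Vim at −0.54 (−0.31 without wild type replicate 1), which also passed so with the block. Lymphoid markers had 1 measured gene and mast cell and basophil markers 0, so neither was tested. Stem and progenitor genes had 8 of 11 positive (adjusted p = 0.682), with Gata2 at −0.42 (−0.18 at its other probe set) and Myc at 0.36 (0.22 without wild type replicate 1). Of the 21 lists, 3 passed with the preset correlation, also with the block and in MAS5, and 0 with an estimated correlation. By fry 0 passed after adjustment.

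The summaries and controls were compared over the same arrays. Differences in GCRMA and MAS5 correlated at 0.70 across the 17028 probe sets, which are not independent replicates. Of the 50 probe sets with the lowest GCRMA p, 50 had the same sign in MAS5, and 40 were lower in the knockdown. The 3′ to 5′ log2 ratio of Gapdh was 0.079 ± 0.076 in wild type and 0.042 ± 0.0098 in the knockdown (two-sided exact permutation p = 0.60). For β-actin it was 1.08 ± 0.11 and 1.05 ± 0.044 (exact p = 0.70). In MAS5 the β-actin ratio was instead higher in the knockdown, by 0.15 (exact p = 0.10). The hybridization controls differed with the groups in GCRMA. At every one, each knockdown array read above the wild type array of the same number. At AFFX-BioB-5_at the groups did not overlap (7.89 to 8.44 in wild type and 8.52 to 9.03 in the knockdown), and at the others they did. This technical difference cannot be separated from the knockdown, and its effect on the results was not tested.

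The arrays also differed in ways the groups do not explain. The first principal component of gene expression held 49.8% of the variance and set both replicate 1 arrays (−42.2 in wild type and −30.7 in the knockdown) apart from the other 4, which lay between 14.9 and 24.3. In addition, long runs of neighbouring genes on chromosomes 3, 12 and 1 were shifted together, in directions that did not follow the groups. The 2 arrays with the same replicate number had the same sign in each run, except for the replicate 3 arrays on chromosomes 3 and 12. In the run from about Sec22b to Rwdd3 on chromosome 3, the median deviation over 39 genes was 0.16, −0.27 and 0.35 in wild type replicates 1 to 3 and 0.14, −0.22 and −0.24 in the knockdown. In the run from about Mpp5 to Ncapg2 on chromosome 12, over 79 genes, it was −0.097, 0.15 and −0.31 in wild type and −0.13, 0.19 and 0.19 in the knockdown. On chromosome 1, from about Dnajb2 to Ro60 and also over 79 genes, it was 0.13, 0.031 and −0.20 in wild type and 0.11, 0.0092 and −0.13 in the knockdown. In each run the range over arrays exceeded that of random sets of as many genes (permutation p = 1e-04, the smallest that 10000 draws can give).

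**Figure D4:**
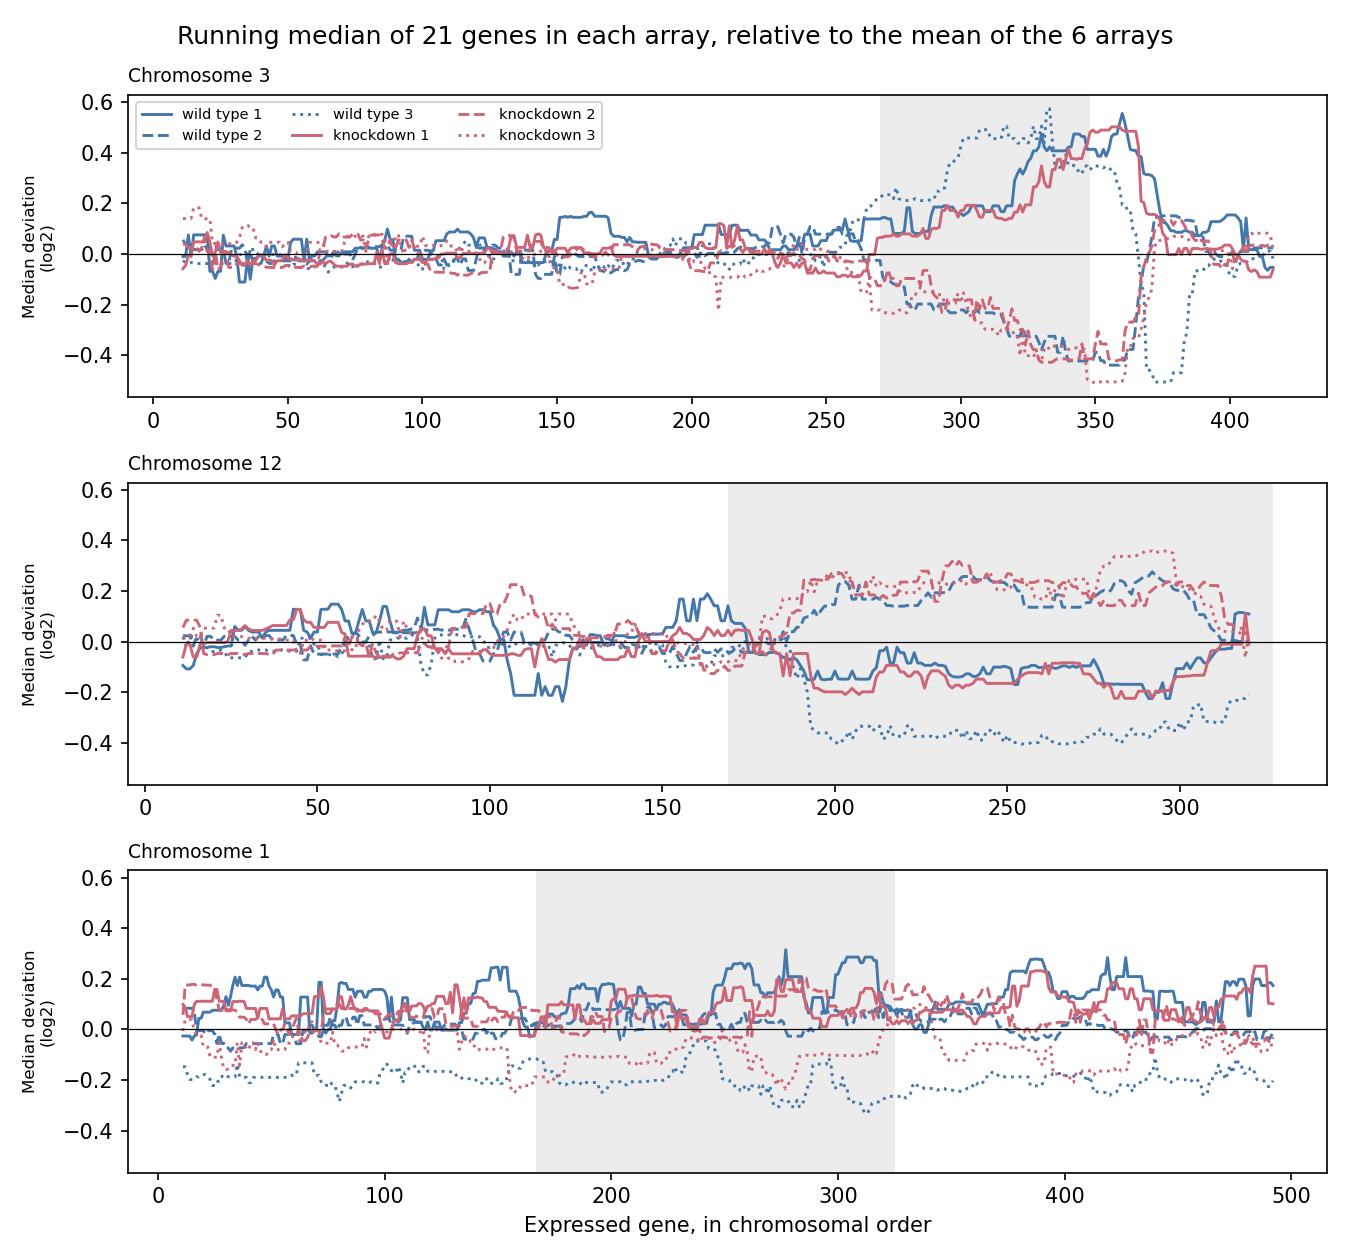
Running median over 21 expressed genes of the GCRMA deviation from the mean of the 6 arrays (log2), against gene order on chromosomes 3, 12 and 1, for each wild type (blue) and knockdown (red) array; grey marks the runs described. On chromosome 3 wild type replicate 3 lies at 0.35 and wild type replicate 2 at −0.27 over the run, so the shift does not separate the groups.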

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

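The tests with both replicate 1 arrays or 3 chromosomes left out, with the estimated correlation plus block, and of the correlation between summaries were chosen after seeing the data. The count of 1 changed probe set became 0 in MAS5, without the filter on dim probe sets, at an adjusted p under 0.01, and with both replicate 1 arrays left out, and ranged from 0 to 1 when single arrays were left out. It became 3 with the filter at log2 6, with array weights, and at an adjusted p under 0.10, in each case both Ehmt2 probe sets and Fis1. With the replicate number as a block (replicate block) it was 2. The brighter Ehmt2 probe set passed with the filter at log2 6 (−2.87, adjusted p = 0.0331), with array weights (−2.85, 0.0387) and with the replicate block (−2.87, 0.0316), and ranged from −3.06 to −2.61 with single arrays left out. Under the filter at log2 6 fewer probe sets, 13820, were tested, and with the block the fit removes differences between replicate numbers. Apart from these and the list-alone counts in the report, the block changed no other call. The cause of the other differences was not tested.

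The count of 3 called lists became 0 with an estimated correlation, with or without the block. It ranged from 1 (without wild type replicate 1) to 4 when single arrays were left out. Equal counts need not hold the same lists. The count was 3 with array weights and with both replicate 1 arrays left out, and 4 without the filter on dim probe sets. In each of these a list called in the main fit lost its call, so lists not called there passed. Which lists these were is not given here. With the estimated correlation the medians of 0.25 (red cell), 0.13 (erythroid transcription factors) and −0.16 (interferon) are unchanged by construction, with adjusted p = 0.859 for each, and 0.822 with the block. The erythroid transcription factor list lost its call with array weights (0.16, adjusted p = 0.0912) and with both replicate 1 arrays left out (0.14, 0.139). The interferon list lost it without the filter (−0.13, 0.059) and without chromosomes 1, 3 and 12 (−0.16, 0.057). With single arrays left out, the medians ranged from 0.17 to 0.37 for the red cell list, 0.096 to 0.20 for the transcription factors and −0.30 to −0.11 for interferon. The cause was not tested.

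Globin counts over all probe sets stayed at 0 under all 15 alternatives, and MAS5 counts at 0 under all 12. Near 0, signs of globin probe sets turned without a call. In MAS5, 1417184_s_at was 0.32 and 1452757_s_at 0.26. With array weights, 1417714_x_at was −0.054 and 1427219_at −0.092. With both replicate 1 arrays left out, 1417184_s_at was 0.0063, 1417714_x_at −0.083 and 1427219_at −0.061. With single arrays left out, 1417184_s_at ranged from −0.13 to 0.038, 1417714_x_at from −0.14 to 0.16, 1427219_at from −0.084 to 0.22, 1428361_x_at from −0.019 to 0.11, 1452757_s_at from −0.14 to −0.030 and 1427866_x_at from −0.70 to −0.031. With array weights 1427866_x_at was −0.56. Wipi2 was −0.036 in MAS5. Of 1031 values of named genes and probe sets under alternatives, the brighter Ehmt2 probe set not counted, 1015 kept their direction, and 53 of these moved by over 1.5 times. Many of these could not turn, since the filters, the variance model and the block leave each difference unchanged by construction. Genes whose groups do not overlap also keep their sign when arrays are left out. The β-actin ratio difference turned from −0.036 to 0.15 in MAS5. The correlation between summaries was 0.78 with a pseudocount of 64, 0.21 without the filter and 0.82 with the filter at log2 6. The correlation was thus lowest with the dim probe sets included, and the cause was not tested.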

Other observations

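All tests in this part were chosen after the results were seen. Expression was also compared between replicate numbers. In a limma fit with group and replicate number, 436 of 9025 genes differed between replicate numbers, among them 22 of 32 cell cycle genes. Replicate 1 differed from replicate 2 at 541 genes and from replicate 3 at 539, and replicates 2 and 3 differed at 0, while MAS5 gave 0 genes for each of these pairs. The median deviation of the cell cycle list from the mean of all arrays was 0.70 in wild type and 0.49 in knockdown replicate 1, −0.094 and −0.24 in replicate 2, and −0.47 and −0.41 in replicate 3. The MAS5 medians had the same signs. By camera with the preset correlation, cell cycle genes were higher in replicate 1 than in replicate 2 (adjusted p = 1.19e-12 over 63 tests), a call lost with an estimated correlation (adjusted p = 0.884). With the preset correlation 6 lists differed between replicates 2 and 3. Among them were the red cell list (camera adjusted p = 8.66e-04) and the erythroid transcription factor list (0.0343). Between replicates 1 and 2 it was 1 list. Between replicates 1 and 3 it was 2, cell cycle and interferon response (camera adjusted p = 0.0151 for interferon response). The 3 lists called for the knockdown thus also differed between replicate numbers. With an estimated correlation 0 lists differed for each pair.

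Among single genes, the mitotic kinase gene Pbk read 9.19 and 8.73 in replicate 1 of wild type and knockdown, against 7.10 to 7.80 in the other arrays (limma adjusted p = 0.0122). Asf1b, which encodes a histone chaperone, read 8.59 and 8.46 against 7.13 to 7.31. Other RNAs were lower in replicate 1. The noncoding RNA Malat1 read 10.44 and 10.09 in replicate 1 and 12.28 to 12.70 in the others (adjusted p = 0.0097), Kcnq1ot1 read 4.58 and 3.92 against 6.17 to 6.75, and Firre 3.41 and 3.43 against 6.01 to 7.10. The kinase gene Clk1 read 9.24 and 9.34 against 10.82 to 11.01. These genes were picked for their values.

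Technical explanations for the distance of the replicate 1 arrays were tested, and no biological explanation was, since the labels do not say what a replicate number stands for. The chromosome blocks described in the report cannot account for it. Without the chromosomes that hold blocks, the smallest distance on the first principal component between a replicate 1 array and another array was 3.76 times the wider range within either set. The 3′ to 5′ control ratios argue against RNA degradation in the replicate 1 arrays, which would raise them: both replicate 1 arrays lay above the other 4 in 0 of 4 readings and below them in the 2 GCRMA readings. RNA degradation in the other 4 arrays (both replicate 1 arrays below in 2 of 4) and a difference in hybridization (both outside in 5 of 9 hybridization controls) stay open.

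The runs on chromosomes 3, 12 and 1 argue against a bias in labelling or base composition that acts as strongly on all chromosomes. A weaker bias could cross the scan's threshold on few chromosomes, so the scan cannot exclude it. A window above the 99th percentile of shuffled gene orders (5.73 as a standardized sum) was found on 3 of 20 chromosomes, at 10.9, −10.5 and −9.59, and the next largest was −5.02. The GCRMA summary was not the source, since the MAS5 medians had the same sign in 6 of 6 arrays for each run, and G9a knockdown was not either, since the 3 wild type arrays alone spanned at least 91.0% of the range. DNA copy number that differs between the cultures, as a leukemia line with subclones may have, is a candidate explanation that expression arrays cannot test. Genes inside the runs had an unadjusted p under 0.05 for the knockdown in 3.27% of cases, against 6.09% elsewhere.

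Of the 11 genes lower in the knockdown with the lowest p, Ehmt2 aside, 6 had a further tested probe set. In 5 of these 6 (Fis1, Atxn10, Eif4ebp2, Uxs1 and Pfn2) a further probe set had the same sign at an unadjusted p under 0.05, which argues against a fault of single probe sets as the source of their direction, though not of the size for Eif4ebp2, where 2 of the 3 further probe sets differed by −0.29 and −0.15 with overlapping groups. The further probe set of 2810004N23Rik differed by −0.057 (limma unadjusted p = 0.685). A fault of single probe sets stays open for 2810004N23Rik and for the 5 genes with 1 tested probe set, Zfp60, A830082K12Rik, Erp29, Zfp120 and Cdc34. Of the 11 genes, 0 lay inside a chromosome run. At an unadjusted p under 0.001, 30 probe sets lay in one direction. Of the 10 splits of the arrays into 3 and 3, 2 gave as many, the real one included, with 44 as the highest other, and among those that part all 3 replicate pairs the others gave 2, 1 and 1. The split with 44 parts 1 pair and set wild type 1, wild type 3 and knockdown 1 against the rest, as the chromosome 3 and 12 runs do. Off-target action of the knockdown construct was not tested, as its sequence is not given in the sources used here.

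With 10 splits of 6 arrays, no count can reach a share under 0.05. For probe sets past the threshold, 1 of the 10 splits, the real one, gave as many as 1, and the highest other gave 0. Among the splits that part all 3 replicate pairs, the fit with the replicate block called 2 probe sets for the real split and 0 for each other. For MAS5 probe sets and for globin probe sets, all 10 splits gave 0. For gene lists, 4 of the 10 splits gave at least the 3 of the real split, and the highest other gave 6. The red cell list itself passed in other splits, with an adjusted p of 7.13e-05 for wild type 1, wild type 3 and knockdown 3 against the rest, below the 4.56e-04 of the real split. Among the splits that part all pairs, it reached 8.09e-05 for wild type 1, wild type 3 and knockdown 2. The interferon list reached 0.0016 for wild type 1, knockdown 2 and knockdown 3, which also parts all pairs, and the erythroid transcription factor list 0.0013 for wild type 1, wild type 3 and knockdown 3.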
